A study of Escherichia coli str. K-12 substr. MG1655 and Escherichia coli with 30 samples.

How the data were processed

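Ribosome footprints (25 libraries) and mRNA (5 libraries) of Escherichia coli K-12 MG1655 with pACYC177 were measured by sequencing. Per the labels' protocols, cells grew at 37 °C in MOPS minimal medium with glycerol and casamino acids, luciferase was induced with 1 mM IPTG, and cells were lysed with chloramphenicol, an inhibitor of elongation. Ribosomes were digested with micrococcal nuclease and taken through a sucrose cushion, per the labels' protocols. The mRNA was extracted with hot acid phenol and depleted of rRNA. Chloramphenicol and micrococcal nuclease both shape where footprints lie along a gene, which a count per gene does not resolve.

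The authors deposited whole-number counts per gene, not normalized, with 4144 genes in the footprint table and 4143 in the mRNA table. Per the submitters' processing notes Bowtie2 2.2.9, DESeq2 1.12.3 and R 3.3.1 were used. The genome build, the annotation, the strand setting and the way reads were counted are not given in the sources used here. Counts of overlapping and antisense genes, and of near-identical pairs such as tufA and tufB or gadA and gadB, are therefore uncertain. Of 4141 locus tags 4140 were found in the reference annotation of assembly ASM584v2, which was used for names alone, and 251 symbols differed from it and were matched by tag. No coordinates are given.

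Samples were grouped by their labels. Tests were run on counts with edgeR 4.0.16 in R 4.3.3, in the sequence filterByExpr, TMM scaling, estimateDisp, a robust quasi-likelihood fit and its F-test, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p threshold of 0.05. C, S, W, H and F were fitted together (15 libraries, 3722 genes), SF and FS apart (6 libraries, 3191 genes), SinF and FinS apart (4 libraries, 3064 genes), and contrasts across series in 1 fit of all 25 (3761 genes). The noncoding ssrA was left out of the tests, and its share is given with the closing observations. Luciferase and the plasmid's resistance genes were kept. Standard errors are those of edgeR's log2 fold changes. Shares of luciferase were compared with a two-sided exact permutation test of their log2 values. Library totals of 848480 to 25456674 footprint counts set the precision of each value. Luciferase in C, at 0, was given a floor of 3 counts per library, and such floors and 95% exact binomial intervals of mRNA shares cover counting error only. Mean levels of lists per library were taken as log2(CPM + 1). Overlap between comparisons with C was set beside that in 20 simulated data sets with unchanged groups.

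The design, the 29 gene lists, the naming rule and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. They were sigma32 chaperones, sigma32 proteases, other sigma32 genes, other folding factors, sigmaE, Cpx and phage shock envelope stress, 50S and 30S ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ribosome rescue and hibernation, amino acid biosynthesis, amino acid transport and catabolism, flagella and chemotaxis, RpoS general stress, acid resistance, cold shock, SOS, oxidative stress, iron acquisition, glycerol use, the TCA cycle, glycolysis and pentose phosphate, ATP synthase and respiration, porins and sugar uptake, the lac operon, nucleotide biosynthesis, and Rcs capsule. Of their members 4 were not found in the tables, ilvG, oxyS, glpR and nmpC. Named genes were, among those with an adjusted p under 0.05, a mean log2 CPM of at least 5 and the same direction in every pair of same-numbered libraries, the 8 with the largest rise and the 8 with the largest fall. Always named were the chaperone list, lon, rpoH, luciferase and the resistance genes, and for each list that passed its 3 members with the smallest p.

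Replicate numbers in series 1 to 3 stand for shared processing and sequencing, per the labels, so they pair the libraries of C, S, W, H and F. Deviations from group means correlated with a mean r of 0.36 over 30 pairs of libraries with the same number (26 above 0.1, lowest -0.0224) and -0.172 over 60 pairs with different numbers. The fit with the number as a block is given beside a result where it changed it. For mRNA, log2 ratios were taken from TMM-scaled CPM with a prior count of 2 over genes with a mean count of at least 10, and footprints per mRNA as the footprint log2 ratio minus the mRNA log2 ratio, without a joint model because each group had 1 mRNA library. The median of a list was ranked among 10000 random lists of the same size matched on expression.

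The edgeR step was tested on simulated data drawn from the real genes' means, dispersions and library sizes, with 200 genes changed by known folds. For F against C (3679 genes) it found 1.52% of genes changed 1.5-fold, 22.7% of those changed 2-fold and 63.6% of those changed 4-fold, or 3.7%, 55.6% and 97.1% at a mean log2 CPM of at least 5, with 1 false call in 63. For SF against FS (3104 genes) it found 13.8%, 53.1% and 93.8%, with 7 false calls in 112, and for SinF against FinS (2979 genes) 16.7%, 67.2% and 98.4%, with 5 in 122. A list shifted by 0.5 on the log2 scale was found in each of the 3 and 0 of 28 other lists were called by camera. Genes were drawn independently of each other, so this does not test for false calls where genes of a list vary together, which the estimated correlation addresses. Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no scaling beyond library size, no filter, a mean of at least 50 counts, the replicate block, other sets of libraries in the fit, leaving out each library, keeping all genes or dropping luciferase and plasmid genes, and thinning to the smallest library. For mRNA they were prior counts of 0.5 and 5, library size alone and a mean of at least 50 counts, and for footprints per mRNA also single footprint replicates. Fits without W replicate 1 in comparisons that do not involve W, and a turned chimera contrast, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.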

Results

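Ribosome footprints were sequenced from Escherichia coli K-12 MG1655 that carried the plasmid pACYC177, either without an insert or with 1 of 8 genes for firefly luciferase, a foreign enzyme that folds with help from chaperones. The series asks how saturated chaperones bear on translation and folding, and each comparison with the empty plasmid asks how the host's own translation differs while a luciferase is made. Footprints are the mRNA fragments that ribosomes shield from micrococcal nuclease, so the count of a gene follows both its mRNA and the ribosomes on it. The cells without an insert were the control, C. The luciferase genes were described as slow (S), wild type (W), harmonized (H) and fast (F), and as slow/fast (SF), fast/slow (FS), slow_in/fast (SinF) and fast_in/slow (FinS), and the labels say nothing further of the last 4. C, S, W, H and F had 3 footprint libraries each, 1 of every group in each of series 1, 2 and 3, which were processed and sequenced together. SF and FS had 3 libraries each in series 4, and SinF and FinS had 2 each in series 5, neither of which held a control. C, S, W, H and F also had 1 mRNA library each. Replicates were numbered without a statement that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

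Total counts ran from 6202441 (W replicate 1) to 25456674 (F replicate 2) in series 1 to 3. They ran from 937606 (SF replicate 2) to 8781449 (FS replicate 1) in series 4, and from 848480 (SinF replicate 1) to 4587614 (SinF replicate 2) in series 5. The mRNA libraries held 874125 to 1545655 counts. W replicate 1 stood apart, with 1388 coding genes at 0 counts, against 127 to 735 in the other 14 libraries of series 1 to 3. Between replicates the biological coefficient of variation was 0.492 in series 1 to 3, 0.2 in series 4 and 0.158 in series 5. These values are common to all genes, and single genes differ.

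Among the inserts of series 1 to 3 luciferase had its highest mean share of translation in F. It held 1.69% ± 0.507 of coding counts in S, 2.06% ± 0.538 in W, 2.04% ± 0.373 in H and 2.98% ± 0.402 in F (SD, n = 3 each), and in each of the 3 series F was above S. No luciferase footprint was counted in C, where a floor of 3 counts per library allows at most 1.96e-05%. The lowest library of S lay at least 62300-fold higher than that floor. The ratio of F to S was 1.8-fold (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 libraries can give). F lay 1.47-fold above W (exact p = 0.2) and 1.47-fold above H (exact p = 0.1). H and W were level at 1-fold (exact p = 1). S lay 1.23-fold below W (exact p = 0.5) and 1.23-fold below H (exact p = 0.4). In edgeR's test F exceeded S by 0.88 ± 0.23 on the log2 scale (adjusted p = 0.139), which did not pass.

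Between the chimeras the shares lay further apart. FS gave 5.29% ± 0.0447 and SF 0.947% ± 0.216 (SD, n = 3 each), a 5.68-fold ratio (exact permutation p = 0.1). FinS gave 4.54% ± 0.292 and SinF 0.563% ± 0.235 (SD, n = 2 each), an 8.44-fold ratio (exact permutation p = 0.333, the smallest that 2 against 2 can give). Over the 8 exact tests of luciferase the lowest Benjamini-Hochberg value was 0.267, since no design here can go below 0.05. The edgeR test, which draws on all genes for its spread, called luciferase lower in SF than in FS (log2 -2.59 ± 0.18, adjusted p = 0.000127) and lower in SinF than in FinS (log2 -3.23 ± 0.31, adjusted p = 0.00291). The kanamycin resistance gene of the plasmid, kanR, was not level between groups. It had a mean of 4.33% of coding counts in C (3.74 to 5.24 over 3 libraries), 6.46% in W (5.42 to 8.21) and 6.3% in F (5.21 to 7.45). It passed in no comparison without the replicate block. With the block it was 1.6-fold higher in W (adjusted p = 0.0456) and 1.61-fold higher in F (adjusted p = 0.0185) than in C. The other resistance gene, ampR, lay the other way, at a mean of 0.258% in C, 0.153% in S, 0.205% in W, 0.179% in H and 0.192% in F. In edgeR's test of S against C it did not pass (log2 -0.69 ± 0.14, adjusted p = 0.242). It passed lower in FinS against C (log2 -0.94, adjusted p = 0.0123), where series differ as well.

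**Figure D1:**
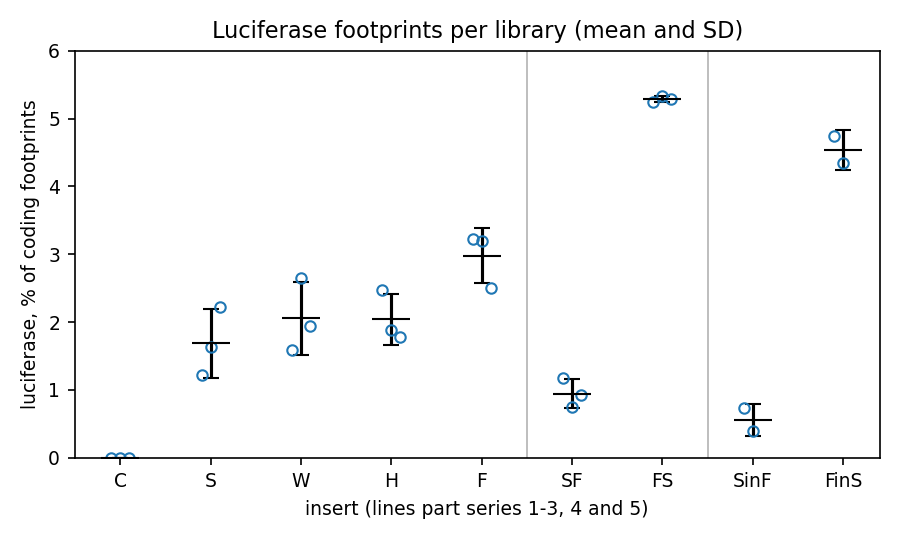
Luciferase footprints as a percentage of coding counts in each of the 25 footprint libraries, by insert, with group means and SD. The control libraries sit at 0, F has a mean of 2.98% against 1.69% in S, and FS and FinS have means of 5.29% and 4.54% against 0.947% in SF and 0.563% in SinF.

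Cells that made the fast luciferase held more footprints on genes of the heat shock response, which sigma32 (rpoH) transcribes, than cells with the empty plasmid. The small heat shock proteins ibpB and ibpA, which bind aggregating proteins, rose 15.8-fold (log2 3.98 ± 0.64 SE, adjusted p = 0.00397, n = 3 against 3) and 8.14-fold (log2 3.02 ± 0.60, adjusted p = 0.018). The disaggregase clpB rose 2.39-fold (log2 1.26 ± 0.18, adjusted p = 0.000785), the Hsp70 chaperone dnaK (dnaK-b0014) 2.33-fold (log2 1.22 ± 0.18, adjusted p = 0.000759) and the chaperonin groL 1.98-fold (adjusted p = 0.00576). The Hsp90 gene htpG (2.24-fold), the redox-regulated chaperone hslO (2.11-fold) and the DnaK partners grpE (1.82-fold) and dnaJ (1.66-fold) brought the number that rose to 9 of the 11 chaperones, or 11 adjusted over the list alone. The other two were groS, 2-fold higher (adjusted p = 0.315, and 4.45e-05 with the replicate block), and hspQ, 1.73-fold higher (adjusted p = 0.349). As a list the chaperones stood above other genes (median log2 1.08, camera adjusted p = 9.66e-20, adjusted p = 0.0237 with an estimated correlation). The footprints of rpoH itself did not pass (log2 -0.08, adjusted p = 0.938).

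Among the proteases that sigma32 controls, 4 of 8 rose in F (6 adjusted over the list alone). They were hslV (2.29-fold) and hslU (2-fold), which form 1 protease, lon (1.89-fold, adjusted p = 0.0281) and the oligopeptidase prlC (1.59-fold, adjusted p = 0.00508). The list gave a camera adjusted p = 1.4e-09, and adjusted p = 0.0367 with an estimated correlation. Of 20 other members of the sigma32 regulon 2 rose, the 23S rRNA methyltransferase rlmE (2.85-fold, adjusted p = 0.00243) and ybeZ (1.67-fold, adjusted p = 0.0152), or 8 adjusted over the list alone (median log2 0.52, camera adjusted p = 1.4e-09, adjusted p = 0.00199 with an estimated correlation). Outside the regulon, mqo, which passes electrons from malate to quinones, rose 2.49-fold (log2 1.31 ± 0.16, adjusted p = 0.000159). The citrate synthase gltA rose 1.62-fold (adjusted p = 0.0105) as the 1 member of 18 in the TCA cycle list that passed (median log2 0.13, camera adjusted p = 0.018, adjusted p = 0.499 with an estimated correlation).

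Some genes of acid resistance and of the general stress response moved the other way in F. The glutamate antiporter gadC fell (log2 -2.21 ± 0.29, 4.64-fold, adjusted p = 0.000271), as did the periplasmic acid chaperones hdeA (log2 -2.03 ± 0.21, 4.08-fold, adjusted p = 3.05e-05) and hdeB (3.73-fold), the membrane protein hdeD (4.43-fold) and the outer membrane lipoprotein slp (3.56-fold). These were 5 of 11 acid resistance genes (8 adjusted over the list alone), with a median log2 of -1.83 (camera adjusted p = 4.81e-14, adjusted p = 0.0118 with an estimated correlation). The list holds the near-identical pair gadA and gadB, whose counts may be split between them and are uncertain. Of 25 genes of the RpoS general stress regulon 9 fell (13 adjusted over the list alone), among them elaB (2.48-fold), osmY (2.31-fold) and wrbA (2.27-fold), with a median log2 of -0.73 (camera adjusted p = 7.09e-19, adjusted p = 0.0118 with an estimated correlation).

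Other falls in F included single genes for maltose uptake, for which no list of their own was fixed. The porin lamB fell 2.9-fold (log2 -1.54 ± 0.21, adjusted p = 0.000487), the maltose-binding protein malE 2.75-fold (adjusted p = 0.000171) and malM 2.46-fold (adjusted p = 0.00486), and with ompC they were 4 of 18 in the list of porins and sugar uptake (5 adjusted over the list alone). That list had a median log2 of 0.01 while its mean was -0.34 and its test pointed down (camera adjusted p = 0.0146, adjusted p = 0.499 with an estimated correlation). In glycolysis and the pentose phosphate pathway 3 of 22 fell, tktB (2.41-fold), talA (2.3-fold) and fbaB (2.02-fold), and the RpoS list also holds tktB and talA. The list had a median log2 of -0.21 (camera adjusted p = 1.7e-06, adjusted p = 0.159 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. The methionine synthase metE fell 2.65-fold (adjusted p = 0.0159).

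In 4 more lists camera passed in F against C although no member did without the replicate block. Flagella and chemotaxis had a median log2 of -1.69 over 42 genes (adjusted p = 8.18e-07, adjusted p = 0.067 with an estimated correlation). Some of them had few counts, with flgF at 0.573 ± 0.765 CPM in F and 5.31 ± 2.05 in C (SD, n = 3 each). Nucleotide biosynthesis had a median log2 of -0.18 over 28 genes (adjusted p = 1.93e-07, adjusted p = 0.0653 with an estimated correlation, 3 lower adjusted over the list alone). With the block its members guaB (adjusted p = 0.0148) and purH (0.0345) passed lower. The 33 proteins of the 50S ribosomal subunit had a median log2 of 0.15 (adjusted p = 0.00599, adjusted p = 0.473 with an estimated correlation). The 15 oxidative stress genes had one of -0.28 (adjusted p = 0.0195, adjusted p = 0.301 with an estimated correlation, 2 lower adjusted over the list alone), and with the block dps (adjusted p = 0.00108) and katG (0.0175) passed lower. The other 17 lists did not pass. Their camera adjusted p was 0.975 for folding factors outside the sigma32 regulon (of which the holding chaperone hchA fell), Cpx envelope stress, the SOS response, glycerol use, the lac operon and Rcs capsule. It was 0.339 for sigmaE envelope stress (of which the periplasmic protease degP, also in the Cpx list, fell), 30S ribosomal proteins, and ribosome rescue and hibernation, and 0.925 for phage shock. It was 0.807 for translation factors, 0.523 for aminoacyl-tRNA synthetases, 0.143 for amino acid biosynthesis, 0.276 for amino acid transport and catabolism, 0.482 for cold shock, 0.281 for iron acquisition, and 0.856 for ATP synthase and respiration. The medians of translation factors (log2 -0.02) and the SOS response (log2 -0.01) were below 0 where the test pointed up.

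Across 3722 genes tested, 61 passed an adjusted p under 0.05 between F and C with edgeR, 22 higher and 39 lower, and 42 of them differed by at least 2-fold. With the replicate number as a block 108 passed, 50 higher and 58 lower, all 61 included. DESeq2 called 125, and without W replicate 1, an alternative chosen after seeing the data, 113 passed. With no scaling beyond library size the median of all genes moved by -0.136 and the split became 17 higher and 59 lower, 22.4% against 36.1% higher. Of 33 genes passing under the naming rule 23 passed in each of the 6 fits that left out 1 of the libraries compared. Among the others dnaJ reached an adjusted p of 0.18 (without F replicate 3), lon 0.178, metE 0.121 and ibpA 0.107 (without C replicate 1), and hslO 0.083 and htpG 0.0609 (without C replicate 3). The largest adjusted p was 0.146 for ybeZ and 0.115 for gltA (without F replicate 2), 0.0592 for grpE (without F replicate 3) and 0.0503 for tktB (without F replicate 1). The calls of 4 lists also ended in such fits, with adjusted p up to 0.205 for 50S proteins (without F replicate 3), 0.226 for oxidative stress and 0.0973 for porins and sugar uptake (without C replicate 2), and 0.339 for the TCA cycle (without F replicate 2).

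**Figure D2:**
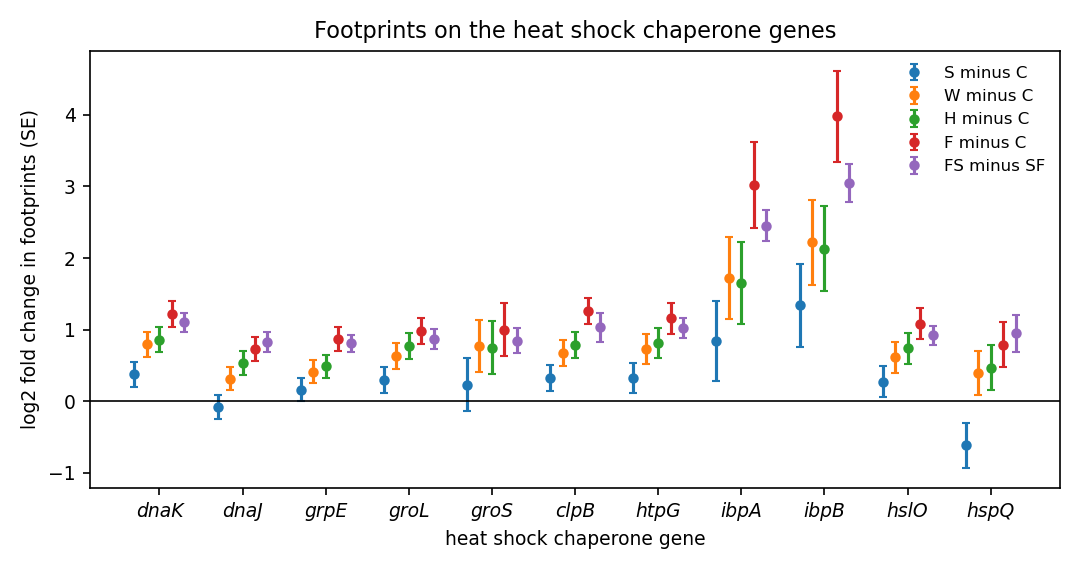
Log2 fold change of footprints with its SE for the 11 sigma32 chaperones in S, W, H and F against the control C (n = 3 libraries each) and in FS against SF (n = 3 each). The values for ibpB are 1.34 in S, 2.22 in W, 2.13 in H and 3.98 in F, and those for dnaK are 0.38 in S, 0.79 in W, 0.86 in H and 1.22 in F, of which dnaK in H and F and ibpB in F passed.

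With the harmonized gene, some acid resistance and general stress genes fell. In H against C the acid resistance genes hdeD (log2 -1.82 ± 0.27, 3.54-fold, adjusted p = 0.00153), slp (3.18-fold, adjusted p = 0.000503), gadC (3.16-fold), hdeB (3.13-fold) and hdeA (2.97-fold) fell (n = 3 against 3). With gadA they were 6 of 11 (8 adjusted over the list alone, camera adjusted p = 6.82e-21, adjusted p = 0.00381 with an estimated correlation). Of the 25 RpoS genes 7 fell and 19 did adjusted over the list alone, among them the pyruvate oxidase poxB (2.22-fold), osmY (2.08-fold) and wrbA (2.03-fold). The list had a median log2 of -0.90 (camera adjusted p = 3.39e-31, adjusted p = 0.0034 with an estimated correlation). Of the chaperones dnaK alone rose, 1.82-fold (log2 0.86 ± 0.18, adjusted p = 0.03), while 9 of 11 passed adjusted over the list alone. The list gave a median log2 of 0.77 (camera adjusted p = 2.37e-16, adjusted p = 0.0452 with an estimated correlation). With the replicate block 8 more chaperones passed, among them ibpB (4.39-fold, adjusted p = 0.00093), groL (1.7-fold, adjusted p = 0.000256), clpB (1.73-fold, adjusted p = 0.000771) and htpG (1.76-fold, adjusted p = 0.000335), as did the protease lon (adjusted p = 0.354 without the block and 0.00646 with it). So did the sigma32 genes hslU (0.00131), prlC (0.0208) and ybeZ (0.0468), while katG (0.00415) and dps (0.00534) of oxidative stress, tktB (0.0258) and sra (0.0468) passed lower with it.

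Further genes that rose in H were rlmE (2.67-fold, adjusted p = 0.00822), hslV (1.87-fold, adjusted p = 0.0449) and mqo (1.76-fold, adjusted p = 0.0234). Further falls were those of yebF (2.3-fold, adjusted p = 0.00285) and ycaC (2.14-fold, adjusted p = 0.0306). The proteases had 1 of 8 higher (median log2 0.44, camera adjusted p = 2.08e-08, adjusted p = 0.0544 with an estimated correlation) and the other sigma32 genes 1 of 20 (camera adjusted p = 0.000118, adjusted p = 0.015 with an estimated correlation). In glycolysis and the pentose phosphate pathway talA and fbaB fell (camera adjusted p = 1.57e-09, adjusted p = 0.0644 with an estimated correlation). Another 7 lists passed camera with no member that passed without the block, at an adjusted p of 0.0544 or more with an estimated correlation. Of 3722 genes 26 passed, 5 higher and 21 lower, against 59 with the replicate block (18 higher and 41 lower, all 26 included) and 60 with DESeq2. The count was 10 without C replicate 1, 12 without C replicate 3, 11, 15 and 6 without H replicates 1, 2 and 3, and 46 without W replicate 1. Of 17 calls under the naming rule 6 passed in each of the 6 fits that left out a library of H or C, those of luciferase, hdeA, hdeB, hdeD, slp and yebF. The calls of mqo (adjusted p up to 0.2) and fbaB (up to 0.266, both without H replicate 3) held in none of them. In 1 fit each held dnaK (up to 0.155) and hslV (0.222, both without C replicate 3) and talA (0.294, without H replicate 1), and in 2 fits ycaC (0.196, without H replicate 3). Those of rlmE, gadC, poxB, osmY and wrbA held in 4, and each ended without H replicate 3 (up to 0.0844). Of 13 list calls 4 ended in such fits, with adjusted p up to 0.416 for 50S proteins (without H replicate 3), 0.165 for ribosome rescue and hibernation (without C replicate 3), 0.406 for the TCA cycle (without C replicate 1) and 0.319 for ATP synthase and respiration (without H replicate 1).

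With the wild-type gene fewer genes passed. In W against C hdeD (log2 -1.59 ± 0.26, 3.01-fold, adjusted p = 0.0191), hdeA (2.3-fold, adjusted p = 0.0191) and hdeB (2.17-fold, adjusted p = 0.0378) fell, as did the periplasmic protein osmY (1.92-fold, adjusted p = 0.0378) and ygiW (1.73-fold, adjusted p = 0.0378), and luciferase was the 1 gene that rose (n = 3 against 3). No chaperone passed over all genes and 8 of 11 did adjusted over the list alone. The chaperone list gave a median log2 of 0.67 (camera adjusted p = 1.22e-12, adjusted p = 0.0872 with an estimated correlation). With the replicate block 8 chaperones passed, among them dnaK (1.73-fold, adjusted p = 0.00014), ibpB (4.67-fold, adjusted p = 0.00133), htpG (1.66-fold, adjusted p = 0.00194) and groL (1.55-fold, adjusted p = 0.00246). The protease gene hslU passed higher (adjusted p = 0.00903), and wrbA (0.0167) and poxB (0.0279) passed lower, with the block as well. Of the acid resistance genes 3 of 11 were lower, 5 adjusted over the list alone, with a median log2 of -1.0 for the list (camera adjusted p = 3.47e-08, adjusted p = 0.0701 with an estimated correlation). The RpoS genes had 1 of 25 lower, 9 adjusted over the list alone, and a median log2 of -0.55 (camera adjusted p = 5.74e-11, adjusted p = 0.0701 with an estimated correlation). The sigma32 proteases (camera adjusted p = 0.000198, adjusted p = 0.254 with an estimated correlation) and other sigma32 genes (camera adjusted p = 2.41e-05, adjusted p = 0.0265 with an estimated correlation) stood higher with no member that passed without the block. Another 4 lists passed camera at an adjusted p of 0.254 or more with an estimated correlation. These 4 calls ended in fits without 1 library, with adjusted p up to 0.326 for 50S proteins (without W replicate 1), and 0.0916 for flagella and chemotaxis, 0.115 for glycolysis and the pentose phosphate pathway and 0.188 for nucleotide biosynthesis (without W replicate 2). With the block oxidative stress passed lower too (median log2 -0.23, adjusted p = 0.0114, against 0.151 without it and adjusted p = 0.602 with an estimated correlation). The 6 calls became 27 with the replicate block (12 higher and 15 lower, the 6 included) and 35 with DESeq2, and 2, 1, 3 and 1 without C replicate 2, C replicate 3, W replicate 1 and W replicate 2. Without W replicate 2 the calls of hdeA (adjusted p = 0.162), hdeB (0.211), osmY (0.256) and ygiW (0.256) ended, and that of hdeD ended without C replicate 3 (0.0738).

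The slow gene gave the fewest calls. In S against C luciferase was the 1 gene of 3722 that passed, with edgeR, DESeq2 and limma-voom alike, while 93 genes had an unadjusted p under 0.05. The values for dnaK (1.3-fold, log2 0.38 ± 0.18, adjusted p = 1), groL (1.23-fold, adjusted p = 1) and ibpB (2.53-fold, adjusted p = 1) did not pass (n = 3 against 3). As a list the chaperones had a median log2 of 0.30 with 0 of 11 members passing (camera adjusted p = 0.0199, 5.27e-07 with the replicate block, and adjusted p = 0.556 with an estimated correlation), and the call ended without C replicate 1 (0.535), S replicate 2 (0.193) or S replicate 3 (0.128). The RpoS list lay lower (median log2 -0.25, camera adjusted p = 2.65e-06, adjusted p = 0.441 with an estimated correlation), with 1 of 25 lower adjusted over the list alone. Another 5 lists passed camera at an adjusted p of 0.441 or more with an estimated correlation. With the replicate block the sigma32 proteases (median log2 0.12, adjusted p = 0.0417) and other sigma32 genes (median log2 0.12, adjusted p = 0.0417) passed higher, which they did not without it (0.122 and 0.107, and adjusted p = 0.556 and 0.508 with an estimated correlation). ATP synthase and respiration (median log2 -0.09, adjusted p = 0.0417) passed lower with it, but not without it (0.074, adjusted p = 0.556 with an estimated correlation). The calls of the 5 lists that passed without the block beside chaperones and RpoS genes ended in fits without 1 library, with adjusted p up to 0.976 for 50S proteins and 0.0711 for amino acid biosynthesis (without S replicate 2), 0.0861 for amino acid transport and catabolism (without C replicate 3), 0.548 for glycolysis and the pentose phosphate pathway (without C replicate 2) and 0.18 for nucleotide biosynthesis (without S replicate 3).

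Calls against the control were shared between inserts. Of the genes called in H and in F, 20 fell in both and, with luciferase left out, 4 rose in both, and 5 fell in W, H and F. All 4 comparisons use the same 3 control libraries, so shared chance values alone can give overlap. In 20 simulated data sets with unchanged groups against those controls the mean overlap of H and F was 0 falls and 0.05 rises, with at most 1. Unchanged groups give few calls, so a low overlap is built in there, and genes were drawn independently of each other. The simulation thus does not show what shared controls give to lists of the observed lengths. Independent lists of the observed lengths, luciferase left out, would share 0.22 falls and 0.0226 rises. The 3 controls cannot be split so that each side keeps a pair, so part of the excess may come from the shared controls. The 20 genes that fell in both H and F became 8, 12 and 11 without C replicates 1, 2 and 3, and 32 without W replicate 1.

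The fast and slow genes, which encode the same protein, were compared directly within series 1 to 3. F also had a higher mean share of luciferase than S in footprints (2.98% against 1.69%, which did not pass) and in mRNA (2.71% against 1.48%). How the protein is encoded and how much of it is made therefore cannot be told apart here. In F against S clpB rose 1.91-fold (log2 0.93 ± 0.18, adjusted p = 0.0276), dnaK 1.8-fold (adjusted p = 0.0306) and dnaJ 1.75-fold (adjusted p = 0.0276), which were 3 of the 11 chaperones (10 adjusted over the list alone, n = 3 against 3). The proteases hslV (1.9-fold), hslU (1.71-fold) and prlC (1.51-fold) rose as well, and so did mqo (1.84-fold, adjusted p = 0.0215). The acid resistance genes hdeD (log2 -1.92 ± 0.27, 3.78-fold, adjusted p = 0.00103), gadC (3.63-fold), hdeA (3.39-fold), slp (3.37-fold) and hdeB (3.36-fold) fell, 5 of 11 (7 adjusted over the list alone). So did malM (2.25-fold), lamB (2.07-fold) and malE (1.98-fold). Camera gave an adjusted p = 7.47e-26 for the chaperones (median log2 0.84, adjusted p = 0.0125 with an estimated correlation), 3.21e-19 for acid resistance (median log2 -1.75, adjusted p = 0.00516 with an estimated correlation) and 2.62e-14 for the RpoS genes (4 of 25 lower, 12 adjusted over the list alone, median log2 -0.55, adjusted p = 0.0174 with an estimated correlation). It gave 2.38e-11 for the proteases (adjusted p = 0.0209 with an estimated correlation) and 3.68e-10 for other sigma32 genes (adjusted p = 0.00166 with an estimated correlation). Amino acid transport and catabolism stood higher with no member called (median log2 0.22, camera adjusted p = 0.000152, adjusted p = 0.0218 with an estimated correlation), and amino acid biosynthesis too (median log2 0.24, camera adjusted p = 1.44e-05, adjusted p = 0.0975 with an estimated correlation). Another 8 lists passed camera at an adjusted p of 0.0798 or more with an estimated correlation.

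Of 3722 genes 22 passed between F and S, 7 higher and 15 lower, with 44 under the replicate block (17 higher and 27 lower, the 22 included) and 56 with DESeq2. With the block the other 8 chaperones passed as well, among them ibpB (6.24-fold, adjusted p = 0.000165), ibpA (4.52-fold, adjusted p = 0.000139) and groL (1.61-fold, adjusted p = 0.000605), as did lon (adjusted p = 0.209 without the block and 0.00205 with it) and the fumarase fumA (0.364 and 0.00727). Passing lower with it were talA (0.0337), fbaB (0.0414) and sra (0.045). Oxidative stress passed lower with it (median log2 -0.14, adjusted p = 0.0403, against 0.0956 without it and adjusted p = 0.386 with an estimated correlation), and the call of ATP synthase and respiration (camera adjusted p = 0.0333, adjusted p = 0.386 with an estimated correlation) ended (0.0522). Of 15 list calls 5 ended in fits without 1 library, with adjusted p up to 0.102 for ribosome rescue and hibernation and 0.373 for porins and sugar uptake (without S replicate 2), 0.345 for iron acquisition and 0.127 for the TCA cycle (without F replicate 2), and 0.397 for ATP synthase and respiration (without F replicate 1). The count was 9, 11 and 6 without S replicates 1, 2 and 3, 7 without each F replicate and 43 without W replicate 1. Of 19 calls under the naming rule 5 held in all 6 unblocked fits without an F or S library. They were hdeA, hdeB, hdeD, slp and gadC. None of the 6 kept clpB (adjusted p up to 0.191), dnaK (0.26), hslV (0.299), prlC (0.225) or osmC (0.229), all without S replicate 1. With the block all 5 passed. The other 9 held in 1 or 2 of the fits, among them dnaJ (up to 0.179) and hslU (0.24, both without S replicate 1), mqo (0.135, without S replicate 3), malM (0.132, without F replicate 3), and lamB (0.142) and malE (0.114, both without F replicate 1).

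The remaining pairs of inserts in series 1 to 3 gave few calls. In H against S 6 genes fell, the acid resistance genes slp (log2 -1.59), hdeB (log2 -1.50), hdeA (log2 -1.31) and hdeD (log2 -1.59), the ribosome-associated protein sra (log2 -1.16) and yebF (log2 -0.97), and none rose (n = 3 against 3). With the block 17 passed and with DESeq2 18, and the count was 3 without H replicate 3. No gene passed between F and W (233 at an unadjusted p under 0.05, 11 with DESeq2, 0 with limma-voom, 8 with the replicate block), between H and W (117, 1, 0 and 0), between W and S (169, 5, 0 and 1), or between F and H (89, 2, 0 and 4) with edgeR. Leaving out W replicate 2 gave 2 genes between F and W and 4 between H and W, and leaving out W replicate 1 gave 1 between W and S. As a list the chaperones stood higher in H than in S (median log2 0.49, camera adjusted p = 1.22e-15, adjusted p = 0.04 with an estimated correlation) and in W than in S (0.40, camera adjusted p = 1.69e-11, adjusted p = 0.149 with an estimated correlation). They also stood higher in F than in W (0.43, camera adjusted p = 2.7e-08, adjusted p = 0.236 with an estimated correlation) and in F than in H (0.35, camera adjusted p = 1.18e-09, adjusted p = 0.342 with an estimated correlation). Between H and W they did not pass (median log2 0.08, camera adjusted p = 0.73). Acid resistance stood lower in H than in S (median log2 -1.50, camera adjusted p = 1.68e-27, adjusted p = 0.0023 with an estimated correlation), and lower in W than in S (median log2 -0.93, camera adjusted p = 4.75e-09, adjusted p = 0.0731 with an estimated correlation). It stood lower in H than in W too (median log2 -0.60, camera adjusted p = 1.34e-06, adjusted p = 0.197 with an estimated correlation) and in F than in W (median log2 -0.78, camera adjusted p = 5.38e-07, adjusted p = 0.156 with an estimated correlation), and did not pass between F and H (camera adjusted p = 0.421). The RpoS list stood lower in H than in S (median log2 -0.60, camera adjusted p = 2.33e-23, adjusted p = 0.00582 with an estimated correlation) and in W than in S (-0.24, camera adjusted p = 0.000142, adjusted p = 0.271 with an estimated correlation). It was lower in H than in W (-0.28, camera adjusted p = 1.34e-06, adjusted p = 0.197 with an estimated correlation) and in F than in W (-0.29, camera adjusted p = 3.97e-05, adjusted p = 0.256 with an estimated correlation), and did not pass between F and H (camera adjusted p = 0.843).

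Other lists passed camera in these pairs as well. In F against W they were sigma32 proteases (2.1e-05) and other sigma32 genes (0.0114), which stood higher, and flagella and chemotaxis (0.00705) and porins and sugar uptake (0.0469), which the test put lower, all with an adjusted p of 0.156 or more with an estimated correlation. In H against W amino acid biosynthesis (adjusted p = 0.00515), ribosome rescue and hibernation (0.0169) and oxidative stress (0.0267) stood lower and ATP synthase and respiration (0.024) higher, with an adjusted p of 0.197 or more with an estimated correlation. In W against S other sigma32 genes stood higher (adjusted p = 0.00034, adjusted p = 0.0395 with an estimated correlation). Sigma32 proteases (0.00295) and amino acid biosynthesis (3.85e-05) stood higher there and glycolysis and the pentose phosphate pathway (0.0214) lower, with an adjusted p of 0.225 or more with an estimated correlation. In F against H other sigma32 genes stood higher (adjusted p = 1.99e-05, adjusted p = 0.0173 with an estimated correlation). Sigma32 proteases (0.00195) and amino acid biosynthesis (0.000395) stood higher, and flagella and chemotaxis (0.000395), nucleotide biosynthesis (0.000545) and porins and sugar uptake (0.032) lower, with an adjusted p of 0.343 or more with an estimated correlation. The medians of porins and sugar uptake in F against W and F against H (log2 0.04 in the latter) were above 0 where the mean and the test pointed down.

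In H against S sigma32 proteases (camera adjusted p = 4.7e-08, adjusted p = 0.0431 with an estimated correlation), other sigma32 genes (0.0032, adjusted p = 0.04 with an estimated correlation) and amino acid transport and catabolism (0.000579, adjusted p = 0.04 with an estimated correlation) stood higher. Ribosome rescue and hibernation, which holds sra, stood lower (7.94e-05, adjusted p = 0.02 with an estimated correlation). Another 7 lists passed camera there at an adjusted p of 0.0581 or more with an estimated correlation. With the replicate block alone further lists passed, none of which did without it (adjusted p of 0.053 or more) or with an estimated correlation. The TCA cycle was higher in F than in W (adjusted p = 0.00531, adjusted p = 0.769 with an estimated correlation), and sigma32 proteases (0.00762) and glycerol use (0.0339) were higher in H than in W (adjusted p = 0.746 for each with an estimated correlation). Translation factors (0.0371, adjusted p = 0.278 with an estimated correlation) and iron acquisition (0.0247, adjusted p = 0.489 with an estimated correlation) were higher in H than in S. ATP synthase and respiration was lower in F than in H (0.0184, adjusted p = 0.639 with an estimated correlation).

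The chimeras of slow and fast parts were compared within series 4. The chaperones were lower in SF than in FS, which held more luciferase footprints. In SF ibpB fell (log2 -3.05 ± 0.27, 8.27-fold, adjusted p = 0.000394), as did ibpA (log2 -2.45 ± 0.22, 5.46-fold, adjusted p = 0.000368), dnaK (log2 -1.10 ± 0.13, 2.15-fold, adjusted p = 0.00223), clpB (2.04-fold, adjusted p = 0.0375), htpG (2.03-fold, adjusted p = 0.00527) and groL (1.82-fold, adjusted p = 0.0133). In all 10 of the 11 chaperones fell, and hspQ did not pass (1.93-fold lower, adjusted p = 0.131, n = 3 against 3). The list had a median log2 of -0.95, with 11 lower adjusted over the list alone (camera adjusted p = 1.7e-22, adjusted p = 0.0807 with an estimated correlation). Of the 8 proteases hslV (2.09-fold), hslU (1.81-fold) and prlC (1.58-fold) fell (7 adjusted over the list alone, camera adjusted p = 2.5e-10, adjusted p = 0.0663 with an estimated correlation). Of the other sigma32 genes fxsA (2.33-fold), ycjF (2.28-fold) and ycjX (1.89-fold) did (camera adjusted p = 1.99e-09, adjusted p = 0.0807 with an estimated correlation). The genes of glycolate use glcB (3.13-fold) and glcG (3.12-fold), and the lactate permease lldP (2.59-fold), were also lower in SF.

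Some acid resistance genes and single genes for maltose use, which had no list of their own, were higher in SF than in FS. The genes malM (3.74-fold, log2 1.90 ± 0.21, adjusted p = 0.00198), malE (3.29-fold, adjusted p = 0.00853), malK (3.25-fold, adjusted p = 0.0195) and malP (2.16-fold, adjusted p = 0.0133) rose, whereas lamB did not pass (log2 1.82, adjusted p = 0.0545). The list of porins and sugar uptake passed (camera adjusted p = 0.000325, adjusted p = 0.595 with an estimated correlation). Of the acid resistance genes slp (3.39-fold, adjusted p = 0.0157), hdeB (3.16-fold, adjusted p = 0.0321) and hdeD (2.59-fold, adjusted p = 0.049) rose, 3 of 11 (9 adjusted over the list alone, median log2 1.66, camera adjusted p = 6.5e-11, adjusted p = 0.39 with an estimated correlation). The RpoS genes aldB (2.12-fold) and elaB (1.64-fold) rose, 2 of 25 (8 adjusted over the list alone, camera adjusted p = 3.34e-09, adjusted p = 0.48 with an estimated correlation). The flagellar genes flgE (5.35-fold), flgF (5.34-fold) and flgC (3.61-fold) rose, 3 of 20 measured (9 adjusted over the list alone, camera adjusted p = 8.53e-09, adjusted p = 0.39 with an estimated correlation). Iron acquisition stood lower (median log2 -0.42, camera adjusted p = 5.68e-05, adjusted p = 0.745 with an estimated correlation), and its call ended without SF replicate 1 (0.768). Glycolysis and the pentose phosphate pathway stood higher (median log2 0.13, camera adjusted p = 3e-04, adjusted p = 0.39 with an estimated correlation). Of 3191 genes 56 passed, 24 higher and 32 lower, against 98 with DESeq2. With no scaling beyond library size the median of all genes moved by 0.106 and the split became 47 higher and 28 lower, 62.7% higher. The count was 34, 26 and 28 without SF replicates 1, 2 and 3, 38 without FS replicate 3 and 22 without FS replicate 2, where slp (0.0935), hdeB (0.16), groL (0.0857) and malK (0.126) no longer passed. Of 35 calls under the naming rule 13 held in each of the 6 fits that left out a library, among them luciferase, ibpA, ibpB, dnaK, htpG, hslO, hslU, hslV, malE, malM, glcB and glcG. Those of prlC (adjusted p up to 0.164, without FS replicate 2), flgF (0.194) and flgC (0.221, both without SF replicate 1) held in none. In 1 fit each held hdeD (0.16), clpB (0.16), ycjX (0.2) and elaB (0.239, all without FS replicate 2), and the other 15 held in 2 to 5, with flgE in 2 (0.16, without FS replicate 2) and malP (0.0626) and lldP (0.087) highest without SF replicate 3. The flagellar genes had few counts, with flgF at 3.65 ± 0.879 CPM in SF and 0.66 ± 0.19 in FS (SD, n = 3 each).

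In series 5 luciferase was the 1 gene of 3064 that passed between SinF and FinS (n = 2 against 2), with 246 at an unadjusted p under 0.05, 11 with DESeq2 and 1 with limma-voom. None of the host genes that follow passed. They were 2.59-fold lower in SinF for ibpB (log2 -1.37 ± 0.22, adjusted p = 0.0644), 1.85-fold lower for dnaK (log2 -0.89 ± 0.26, adjusted p = 0.448), 2.18-fold higher for slp (adjusted p = 0.0644) and 1.95-fold higher for hdeB (adjusted p = 0.0993). As lists the chaperones stood lower (median log2 -0.84, 8 of 11 adjusted over the list alone, camera adjusted p = 1.23e-11, adjusted p = 0.545 with an estimated correlation) and acid resistance higher (median log2 0.94, 6 of 11 adjusted over the list alone, camera adjusted p = 3.51e-11, adjusted p = 0.505 with an estimated correlation). The RpoS genes stood higher (median log2 0.34, camera adjusted p = 2.51e-08, adjusted p = 0.505 with an estimated correlation). Amino acid biosynthesis, led by leuA (2.17-fold lower, adjusted p = 0.174), stood lower (median log2 -0.32, camera adjusted p = 7.45e-09, adjusted p = 0.582 with an estimated correlation). So did the TCA cycle (median log2 -0.44, camera adjusted p = 2.51e-08, adjusted p = 0.625 with an estimated correlation). Another 7 lists passed camera at an adjusted p of 0.505 or more with an estimated correlation. Without SinF replicate 1, which had the lowest total, 33 genes passed. The count was 164 without SinF replicate 2, 4 without FinS replicate 1 and 2 without FinS replicate 2. These fits assume that the lone library of a group varies like the other group. In them 3 of 12 list calls ended, with adjusted p up to 0.338 for sigmaE envelope stress and 0.0964 for flagella and chemotaxis (without SinF replicate 2) and 0.854 for aminoacyl-tRNA synthetases (without SinF replicate 1). With no scaling beyond library size the median of all genes moved by 0.169 and 6 genes were higher and 1 lower.

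The direction of the chimera difference was set against that of fast and slow. Each of the 22 genes called between F and S had the opposite sign in SF minus FS, and 14 of them were called there. In SinF minus FinS 19 of 22 had the opposite sign. Across 3190 genes, which are not independent replicates, the log2 fold changes of F minus S and SF minus FS had a Pearson r of -0.454 and a Spearman rho of -0.372, from libraries that do not overlap. A test of the difference of the differences over all 25 libraries called 101 of 3761 genes, 61 higher and 40 lower. Of the 99 tested in both comparisons 14 were called in each, 34 in 1 of them and 51 in neither, so the call alone does not show that both sides changed. The 101 held 10 of 11 chaperones lower (median log2 -1.83) and 8 of 11 acid resistance genes higher (median log2 3.31). With no scaling beyond library size it gave 97 higher and 37 lower, 72.4% higher, and the median of all genes moved by 0.15. The same test between series 5 and series 4 called 0 genes with edgeR (57 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom), and 1 without SinF replicate 2.

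Against the control the chimeras differ in series as well as in insert, and these cannot be told apart. In FS 81 genes passed, among them ibpB (log2 3.75 ± 0.56, adjusted p = 0.000657), dnaK (log2 1.27 ± 0.19, adjusted p = 0.000271) and slp (log2 -1.94 ± 0.23, adjusted p = 1.63e-05). There 9 of 11 chaperones were higher (median log2 1.11) and 6 of 11 acid resistance genes lower (median log2 -1.72, n = 3 against 3). In FinS 30 genes passed (n = 2 against 3), with 1 chaperone, ibpB (log2 2.55, adjusted p = 0.0394), higher and 3 acid resistance genes lower. In SF luciferase was the 1 gene that passed, and in SinF luciferase, melA (log2 -2.86) and hemB (log2 -0.81) passed, and the host genes among them were chosen after their values were seen. The chaperone medians of SF (log2 0.21) and SinF (log2 -0.02) held no member that passed. The count for SF was 2 without SF replicate 3. That for FS was 51 without FS replicate 2 and 158 without W replicate 1. That for FinS was 11 without C replicate 2, 4 and 3 without FinS replicates 1 and 2, and 71 without W replicate 1. That for SinF was 140 without SinF replicate 2 and 6 without W replicate 1.

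**Figure D3:**
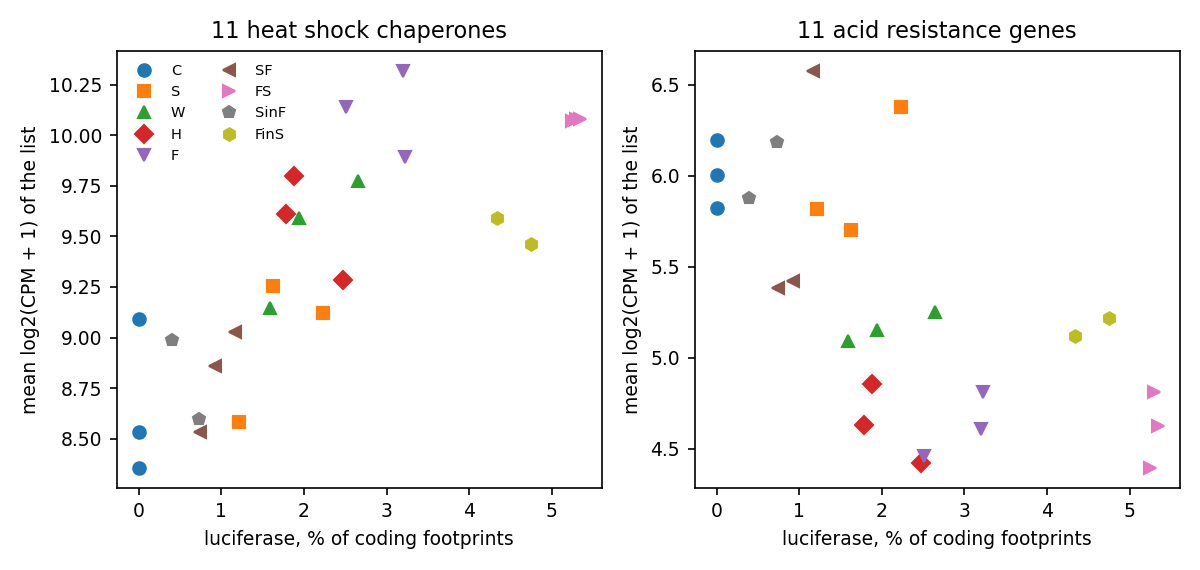
Mean log2(CPM + 1) of the 11 sigma32 chaperones and of the 11 acid resistance genes against luciferase footprints as a percentage of coding counts, 1 point per footprint library, for all 25 libraries by insert. The chaperone values of SF lie between 8.535 and 9.028, within the range of the controls (8.355 to 9.094), and those of FS lie between 10.07 and 10.08, within the range of F (9.895 to 10.32), whereas those of FinS, at 4.34% and 4.75% luciferase, are 9.593 and 9.463, below each library of F.

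The mRNA libraries, 1 per group and so without replicates, were described without a test. Luciferase took 1.48% of mRNA counts in S (95% exact binomial interval 1.45 to 1.5), 2.1% in W (2.07 to 2.12), 1.48% in H (1.46 to 1.5) and 2.71% in F (2.68 to 2.74). In C it had 0 counts, which allows up to 0.000283%. Such intervals and floors cover counting error only. The share of footprints divided by the share of mRNA was 1.14 ± 0.343 in S, 0.983 ± 0.257 in W, 1.38 ± 0.253 in H and 1.1 ± 0.148 in F (SD over 3 footprint libraries, 1 mRNA library).

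Chaperone mRNA was higher in the library of every insert than in that of C. The median log2 ratio of the 11 genes was 0.30 in S, 0.52 in W, 0.88 in H and 1.23 in F, each above all of 10000 random lists matched on expression (percentile 100), with all 11 members above 0. All 4 ratios use the same library of C and are not independent of each other, genes of 1 regulon vary together where those of random lists need not, and percentiles describe these libraries alone. In F the mRNA of dnaK was higher by 1.36 on the log2 scale (counting interval 1.33 to 1.43), next to 1.21 for its footprints, and groL by 1.25, next to 0.98. For clpB the mRNA value was 0.38 and the footprint value 1.25, and for ibpB 1.85 and 4.16. The acid resistance genes that were measured, 8 in number, had median mRNA log2 ratios of -0.29 in S (percentile 4.26), -1.44 in W (percentile 0), -1.09 in H (percentile 0) and -1.94 in F (percentile 0), with hdeA at -1.81 and slp at -1.88 in F. The 22 RpoS genes lay at -0.07 in W (percentile 11.7), -0.14 in H (percentile 2.61) and -0.38 in F (percentile 0), and at percentile 52.1 in S.

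Footprints per mRNA were taken for the same groups. For the chaperones the median log2 of footprints per mRNA was -0.08 in S (percentile 41.4 of matched random lists), 0.13 in W (89.9), -0.06 in H (33.8) and -0.06 in F (56.6). For the 8 acid resistance genes it was 0.31 in S (87.5), 0.48 in W (98.7), -0.16 in H (20.6) and 0.56 in F (97.8). For the RpoS genes it was -0.20 in S (1.54), -0.49 in W (0.06), -0.73 in H (0) and -0.45 in F (0). For osmY the values in F were an mRNA ratio of -0.20 and a footprint ratio of -1.24. In F the iron acquisition genes had more mRNA (median log2 0.42, percentile 100) and fewer footprints per mRNA (median log2 -0.43, percentile 0.04). Nucleotide biosynthesis (median log2 -0.37) and glycolysis and the pentose phosphate pathway (median log2 -0.36) lay at percentile 0 for footprints per mRNA in F. Across 1955 genes, which are not independent replicates, the log2 ratios of mRNA and footprints against C had a Pearson r of 0.0048 in S, 0.0785 in W, 0.212 in H and 0.332 in F (Spearman rho 0.0287, 0.0663, 0.16 and 0.18). These ratios share the control libraries within each assay but not between assays.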

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

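The tests by splits of the libraries, plasmid share, series, luciferase amount in series 1 to 3, turning the chimera difference and exchanged names were chosen after the results were seen, whereas those by thinning and by distinct fragments in W replicate 1 were set before.

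SF minus FS differed from F minus S for 101 genes, by a test of the difference of the differences over all 25 libraries. Of the 99 tested in both comparisons each had opposite signs, which the selection favours, and 14 were called in both, 34 in 1 and 51 in neither. On the log2 scale, as (SF minus FS) minus (F minus S), the chaperones were negative, with ibpB at -5.68, ibpA at -4.6, hspQ at -2.31, clpB at -1.93, dnaK at -1.92, htpG at -1.83, hslO at -1.69, dnaJ at -1.61, groL at -1.52 and grpE at -1.48. Other sigma32 genes were negative too, with ycjF at -2, hslV at -1.95, ycjX at -1.83, hslU at -1.6, lon at -1.36, prlC at -1.23 and ybeZ at -1.17. Luciferase itself was at -3.44, the glycolate genes glcG and glcB at -2.79 and -2.43, the lactate permease lldP at -2.32, yobA at -2.13, mqo at -1.94 and ampR at -1.01. Acid resistance genes were positive, with slp at 3.55, hdeA at 3.53, hdeB at 3.44, hdeD at 3.31 and gadC at 3.22. So were the maltose genes malM at 3.11, lamB at 2.9, malE at 2.73, malK at 2.38 and malP at 2.05. Of the RpoS list, osmC was at 1.83, elaB at 1.66, wrbA at 1.62, tktB at 1.4, osmY at 1.32 and talA at 1.29. From other lists, sra was at 1.53 and fbaB at 1.43. The flagellar gene flgE was at 3.37, bfr at 2.18, yegP at 2.13, metE at 2.03, cydB at 0.911 and pgl at 0.829.

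Of 100 splits of the libraries, the real one included, 1 gave as many genes as the real 101. The highest of the others gave 14. The 80 splits that part the 3 pairs of F and S gave the same (1 as many, highest other 14). These counts argue against chance in how these libraries fall into groups. Mixed splits put any real group difference into the spread, which lowers their counts. Chance between cultures was not tested, because the replicates may be technical. With all libraries thinned to 1 total 79.2% of the 101 genes kept their sign and their call, which argues against depth as the whole cause. With the chimera difference turned to FS minus SF, the insert with more luciferase footprints came first on both sides. EdgeR called 0 genes (47 at an unadjusted p under 0.05, no other tool run). The opposite direction rests on which chimera is put first, which the labels do not settle. For the 101 the 0 decides nothing, as the unturned test picked them. In series 5 FinS exceeded SinF in luciferase by 3.08 on the log2 scale, and with n = 2 no host gene passed between them with edgeR (246 genes at an unadjusted p under 0.05, 11 called with DESeq2), while the test between series 5 and 4 called 0 genes with edgeR (57 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom), so no difference between those series was shown. The amount of luciferase, exchanged names of SF and FS and a true difference between these inserts cannot be told apart. Luciferase footprints go with the insert, and no gene counted marks the inserts. The order of slow and fast parts stays open as an untested explanation.

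For the rise of the sigma32 chaperones in F against C, the median log2 fold change without luciferase and plasmid genes and without scaling was 1.01, and within series 1, 2 and 3 it was 1.2, 0.956 and 1.24 with 11 of 11 higher in each, which argues against the plasmid's share and the series as the whole cause. Over the 12 libraries of S, W, H and F, centred by series, the mean chaperone level rose with the log2 luciferase share (Pearson r 0.81, two-sided exact permutation p = 0.00485 over 13824 rearrangements within series, adjusted 0.0145 over 3 relations, and Spearman rho 0.846, p = 0.0103, adjusted 0.0308). These 12 libraries are 3 of each of 4 inserts, and were rearranged within each series as if libraries of an insert were unrelated. The p-values of these relations therefore do not measure a relation across the 4 inserts. Without the 2 libraries farthest from the median share r was 0.643, and within the series of 4 libraries each it was 0.95, 0.88 and 0.358. The same relation did not pass for acid resistance (r -0.468, exact permutation p = 0.111, adjusted 0.111, rho -0.517, p = 0.0805, adjusted 0.0805) or, after adjustment, for RpoS genes (r -0.526, exact permutation p = 0.0972, adjusted 0.111, rho -0.615, p = 0.0413, adjusted 0.062), where series 3 gave 0.0882 and 0.154. A candidate explanation within series 1 to 3 is that chaperone translation follows the luciferase made, although FinS, in another series, held 4.34% and 4.75% luciferase with mean chaperone levels of 9.593 and 9.463, below each library of F (9.895 to 10.32), and the codons of the inserts, which differ as well, stay open as an untested explanation.

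W replicate 1 had 1388 coding genes at 0, and of the other libraries of series 1 to 3 thinned to its total C replicate 3 had the most, 755, which argues against depth as the whole cause. For few distinct fragments, counts would scatter around their expectation at least 3 times as much as in the highest other library, and at most 1.5 times as much otherwise. The ratio was 0.392 and so met the second bound, but that bound was set aside after its value had been seen, because 3 genes carried 89.3% of the scatter of the library it was set against, C replicate 2. Without that library the ratio was 2.82, against F replicate 1, between the bounds, so few fragments and another origin cannot be told apart. No biological explanation was tested.

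The noncoding ssrA, the tmRNA that frees stalled ribosomes, took 3.9% of all counts in the lowest library of SinF, above the highest control library at 3.02%, with means of 4.67% ± 1.09 in SinF (SD, n = 2) and 2.15% ± 0.752 in C (SD, n = 3), whose series differ. FinS, of the same series as SinF, had 2.28% ± 0.074 (SD, n = 2), and W replicate 3 at 3.4% also lay above the highest control library.

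The libraries of a pair of groups of 3 make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in S against C (1, highest other 0), W against C (6, highest other 1), H against C (26, highest other 0), F against C (61, highest other 0), F against S (22, highest other 0) and H against S (6, highest other 0). It was also the 1 in SF against FS (56, highest other 0), SF against C (1, highest other 0) and FS against C (81, highest other 1). In F against W, H against W, W against S and F against H the real count was 0 with edgeR and 10 of 10 splits gave as many, with 0 in each other split. In series 1 to 3, where numbers pair the libraries, 4 splits part all 3 pairs, and those other than the real one, which exchange the groups within some of the series, called 0 genes in each comparison.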

How the results depend on the processing

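The fits without W replicate 1 in comparisons that do not involve W and the settings of the overlap were chosen after seeing the data. The cause of a change was not tested, except where a setting removes genes or libraries by construction. Of the values that answer a comparison 373 kept their direction and their side of the threshold or stayed within 1.5 times, 110 moved, 9 lost a call and 0 reversed. DESeq2 called 35 genes in W, 60 in H and 125 in F against C, 56 in F against S, 11 in F against W, 1 in H against W, 5 in W against S, 18 in H against S and 2 in F against H. It called 98 in SF against FS, 11 in SinF against FinS, 1 in the difference between series 5 and 4, and against C 6 in SF, 162 in FS, 42 in SinF and 117 in FinS. With the replicate block 27 passed in W, 59 in H and 108 in F against C, 44 in F against S, 8 in F against W, 1 in W against S, 17 in H against S and 4 in F against H. In S, W, H and F against C and in F against S the block changed no call of a gene under the naming rule or of a list other than those named or counted in the report. Against C it gave 2 in SF, 147 in FS, 15 in SinF and 87 in FinS. SF and FS share only numbers, as do SinF and FinS. With the block 23 genes passed between SF and FS, 22 of the 56 among them, and 54 between SinF and FinS. Deviations of same-numbered libraries had a mean r of 0.015 in the first pair of groups, where not every library correlated best with its own number, and 0.00244 in the second.

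With no scaling beyond library size rpoH reversed in F minus S (-0.0259) and in SF minus FS (0.0695) and hspQ in SinF minus FinS (0.136), none of them called. That setting gave 1 gene in F against W, 2 in F against H, 7 in SinF against FinS, 1 in the difference between series 5 and 4, and 2 in SF and 158 in FS against C. All 25 libraries in 1 fit gave 15 in W and 92 in F against C. With luciferase and plasmid genes dropped, which takes luciferase out of the calls by construction, 0 remained in S against C, SinF against FinS and SF against C with edgeR, and 1 in SinF against C. With limma-voom 13 genes passed in W and 7 in FinS against C, and with no filter 39 in SinF against FinS. Thinned to the smallest library, 2 passed in SinF against FinS and 2 in SF against C, and with a mean of at least 50 counts 2 in SF and 5 in SinF against C. Only the groups compared, which leaves fewer libraries to estimate the spread, gave 1 in W against C, 6 in F against S, 1 in H against W, and 8 in SinF and 51 in FinS against C. The overlap of falls in H and F against C became 37 with DESeq2, 34 with the replicate block and 13 when thinned. The correlation of F minus S with SF minus FS across genes was -0.653 at a mean log2 CPM of at least 5.

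With an estimated correlation the chaperone list lost its call in S (adjusted p = 0.556) and W (0.0872) against C, in SF minus FS (0.0807) and in SinF minus FinS (0.545), and with fry in S against C (0.779) and SinF minus FinS (0.266). It also lost it with an estimated correlation and with fry in F minus W (0.236 and 0.232), W minus S (0.149 and 0.31) and F minus H (0.342 and 0.425), and with fry in H minus S (0.0971). By library size alone the median mRNA log2 ratio of the chaperones was 0.237 in S, 0.477 in W, 0.802 in H and 1.06 in F. From 1 footprint replicate their footprints per mRNA were 0.265 in W (replicate 3), 0.105 in H (replicate 1) and -0.274 in F (replicate 2). Luciferase was 5.2% of all counts in FS.

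Without 1 library at a time, counts ran from 1 to 7 in W, 6 to 46 in H and 41 to 113 in F against C, 6 to 43 in F against S, 0 to 1 in W against S, 3 to 7 in H against S, 0 to 2 in F against W and 0 to 4 in H against W. They ran from 22 to 67 in SF against FS, 2 to 164 in SinF against FinS, 0 to 1 in the difference between series 5 and 4, and against C 1 to 2 in SF, 51 to 158 in FS, 2 to 140 in SinF and 3 to 71 in FinS. The overlap ran from 8 to 32. Log2 values that reversed, none of them called, ran from -0.000782 to 0.487 for groS in S against C, -0.116 to 0.0244 for rpoH in W against C, -0.271 to 2.3 for aceK in F against S, -0.104 to 0.12 for rpoH in SF minus FS, and -0.463 to 0.396 for hspQ and -0.075 to 0.244 for rpoH in SinF minus FinS. Adjusted p ran from 1.32e-05 to 0.535 for the chaperones in S against C, and in a pair of lists whose direction reversed from 0.000274 to 0.976 for 50S proteins in S against C and 4.67e-10 to 0.854 for aminoacyl-tRNA synthetases in SinF minus FinS. Over all settings 5542 values of named genes kept direction and side of the threshold, 271 gained a call, 326 lost one and 10 reversed. A further 56 were not given, because the setting left the gene out or gave no adjusted p. Of the values of lists other than the chaperones 738 kept both, 191 lost the call and 2 reversed. Depth limits weakly counted genes in SinF replicate 1 (848480 counts) and SF replicate 2 (937606 counts).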

Other observations

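Genes here were chosen after their values were seen. Tests of mqo and malE are above, none of flu. The surface adhesin flu (antigen 43), whose expression is switched on or off in single cells by phase variation, varied widely between libraries of C, S and F. In W it stood at 3690 ± 631 CPM and in H at 123 ± 13.4 (SD, n = 3 each). In F the 3 libraries held 3100, 2980 and 309 CPM, in S 84.4, 574 and 77.2, and in C 314, 1540 and 188. All chimera libraries lay between 49.9 and 114 CPM.

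Footprints of mqo, which passes electrons from malate to quinones, stood at 121 ± 13.1 CPM in C, 297 ± 56.1 in F and 297 ± 24 in FS (SD, n = 3 each). In FinS, which also held many luciferase footprints, they stood at 145 ± 6.83, and in SinF at 98.3 ± 17.5 (SD, n = 2 each). The maltose-binding protein malE stood at 590 ± 108 CPM in C and 591 ± 135 in SF, against 212 ± 44.6 in F and 179 ± 51.5 in FS (SD, n = 3 each), with 260 ± 35.7 in FinS and 321 ± 87.2 in SinF (SD, n = 2 each). F and FS came from different series.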
